A study of Mus musculus with 6 samples.

How the data were processed

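Gene-level read counts of 6 lung RNA-seq libraries were analysed, 3 from female BALB/c mice given NTCU and 3 from mice given saline. Carcinoma had been established by histology and immunohistochemistry, and 3 tissues per group were chosen at random, per the labels. RNA was isolated with a kit, freed of genomic DNA, had integrity numbers above 6.8 and was made into libraries with the NEBNext Ultra RNA kit, per the labels. The tools named are STAR 2.5, HTSeq 0.6.1 and DESeq2, and the builds GRCm38 and mm10, per the submitters' processing notes, which do not give the role of each tool. The deposited files hold 1 integer count per Ensembl gene and library, taken here as reads assigned to that gene. The whole-series table holds the same values as the files of the single samples and was not used here. The strand setting and the annotation release of the counting step are not stated in the labels, so reads of overlapping or antisense genes may be counted with their neighbours.

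Of 35275 genes in the files 34490 were matched by identifier to symbols of GENCODE M21, the source of the coordinates, and 785 were not. Total counts per library ran from 16254496 to 19517815. At these depths 3 counts, the 95% upper limit for a count of 0, correspond to 0.154 to 0.185 CPM (counts scaled to a common library size). For genes at 0 counts in a whole group the fold is given as a lower bound from 3 counts over that group's libraries together. For 1 to 3 counts in a group a ratio with a 95% counting interval is given. These bounds and intervals cover counting error only, not differences between animals. CPM values were computed from the deposited counts with TMM factors, which were 0.864, 1.01 and 0.967 in NTCU replicates 1, 2 and 3 and 1.06, 1.04 and 1.07 in saline replicates 1, 2 and 3.

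Groups were compared in R 4.3.3 with edgeR 4.0.16 (filterByExpr on the group, TMM, robust quasi-likelihood fit, quasi-likelihood F test, 2-sided), with Benjamini-Hochberg adjustment over the 15494 genes kept and a threshold of 0.05. Values after ± are standard errors (SE) of log2 fold changes or standard deviations (SD) of 3 lungs, as marked. The median biological coefficient of variation was 0.259. Shares of counts were compared with a 2-sided exact permutation test, which for 3 against 3 cannot give a p under 0.1. The genes tested, the gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. There were 50 lists with 1050 entries, of which 4 were matched by an older symbol or synonym and 7 had no gene in the files. The 49 lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the lists. The list of sex-linked genes served as a check of the labels and was not tested. Camera asks whether a list's genes differ from all other genes. Each list test was repeated with the correlation estimated from the data and with fry. Counts "adjusted over the list alone" use the same gene p values adjusted within the list.

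The pipeline was tested on simulated data drawn from the means, library sizes and dispersions of these libraries. The filter removed 1 of 200 genes given a change and kept 15293 genes. Of these 17 of 99 with a 2-fold change and 71 of 100 with a 4-fold change were recovered. The 99 calls also held 5 of 24 members of a list moved 2-fold as a whole and 6 unchanged genes. With DESeq2 43 of 187 calls were unchanged genes and with limma-voom 5 of 89, and camera called 1 list, the moved one. Both groups were drawn with the same dispersion of each gene, so a larger spread between NTCU lungs was not simulated. Far fewer genes were changed than were called in the real comparison. The shares recovered and the false calls therefore need not carry over to the real libraries. Each gene was drawn independently of the others, so the simulation does not test camera's preset correlation on lists of correlated genes. The correlation estimated from the real data was 0.641 for basal and squamous epithelium and 0.445 for cholesterol biosynthesis. Alternatives were RLE, upper quartile and total-count scaling, DESeq2 1.42.0, limma-voom with and without quality weights, a fit that was not robust, other filters and thresholds, removal of mitochondrial, hemoglobin and immunoglobulin genes, a block for the replicate number, and leaving out each library in turn. A loess correction of log2 CPM on GC content and transcript length (span 0.5) was added after the data had been seen.

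Genes are named by a fixed rule. The first part takes the 12 largest rises and 12 largest falls among protein-coding genes past the threshold whose groups do not overlap and whose mean in the higher group is at least 5 CPM. The second takes up to 4 members of each list with the smallest p. The third is a fixed set (Krt5, Krt14, Trp63, Sox2, Sftpc, Scgb1a1, Mki67, Abca1, Col1a1, Cdkn1a and the sex-linked genes among others). Some genes that the rule takes are not reported here. Scgb3a1, Cldn10, Chad, Aox3, Hbb-bs, Ear1, Fabp1, Siglecf, Ear2, Krt79, Car4, Nos2, Vcan, Itgb2, Junb and Eno1 are outside the rule and were chosen after their values had been seen, as were the genes of the added lists in the closing section and Pmvk. No library was left out of the main comparison.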

Results

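Lung RNA was sequenced from 6 female BALB/c mice. In 3 of them lung squamous cell carcinoma had been induced with N-nitroso-tris-chloroethylurea (NTCU), a carcinogen painted on the skin, and the other 3 had received saline. NTCU was given at 0.04 M and saline at 0.9%, in both cases 25 µL per application and 2 applications per week, 3.5 days apart, for 30 weeks. Assigned reads totalled 17873074, 17960620 and 17046625 in NTCU replicates 1, 2 and 3, and 16254496, 18810286 and 19517815 in saline replicates 1, 2 and 3. At these depths a count of 0 in 1 library allows a level of up to 0.154 to 0.185 CPM (counts scaled to a common library size, taking 3 counts of the library's total), a limit that covers counting error only. Xist had between 3340 and 8362 counts in the 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each of them. Transcripts of Scgb1a1, the club cell secretory protein, made up 0.375% ± 0.428 (SD, n = 3) of counts in NTCU lungs and 3.53% ± 0.507 (SD, n = 3) in saline lungs. Hemoglobin transcripts made up 0.0834% ± 0.0276 in NTCU and 0.288% ± 0.0414 in saline lungs. In both cases the 2-sided exact permutation p was 0.1, the smallest that 3 animals against 3 can give. The share of immunoglobulin transcripts was 1.13% ± 0.812 in NTCU and 0.243% ± 0.129 in saline lungs (exact permutation p = 0.2), and that of mitochondrially encoded transcripts 2.48% ± 0.234 and 2.69% ± 0.872 (exact permutation p = 0.7). Across genes, which are not independent replicates, Pearson's r of log2 (CPM + 1) was between 0.994 and 0.995 within the saline group and 0.994 between NTCU replicates 2 and 3, but 0.972 and 0.977 between NTCU replicate 1 and the others.

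The comparison of NTCU with saline lungs asks which genes differ between lungs with induced squamous carcinoma and normal lungs. Genes of basal and squamous epithelium rose (14 of 23 measured), with the basal keratin Krt5 at 173 ± 161 CPM (SD, n = 3) in NTCU lungs and 0.108 ± 0.0636 CPM in saline lungs. Enzymes of cholesterol synthesis (15 of 24 measured), targets of p53 (11 of 23) and genes of an alveolar macrophage list (11 of 23) also rose. Among them were Cyp51 3.79-fold, Cdkn1a 8.05-fold and Gpnmb 22.6-fold. In the macrophage list Ear1 fell, and 6 of 23 members, Ear1 among them, had a log2 fold change below 0. Genes of endothelial cells fell (17 of 24), with Tek, the angiopoietin receptor, at 55.2 ± 26.0 CPM in NTCU lungs and 432 ± 8.80 CPM in saline lungs. Each of these 5 lists passed camera's test at its preset correlation and none at an estimated correlation between genes (adjusted p between 0.329 and 0.564). The surfactant protein gene Sftpc and the proliferation marker Mki67 did not pass the test, with fitted log2 fold changes of -0.00 ± 0.28 (SE; adjusted p = 0.995) and 0.40 ± 0.42 (adjusted p = 0.579). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1232 of 15494 genes tested changed at an adjusted p under 0.05, 680 higher and 552 lower in NTCU. Of these, 923 changed at least 2-fold (485 higher, 438 lower). In 5895 genes (38.0%) the values of the groups did not overlap, which chance gives in 10% of genes for 3 libraries against 3, and all 1232 changed genes were among them. The count depended on single libraries. It was 3233 without NTCU replicate 1, 194 without NTCU replicate 3 and 0 without saline replicate 1, 2 or 3. In the latter fits edgeR gave 2842, 2951 and 2832 genes at an unadjusted p under 0.05, DESeq2 called 1479, 1517 and 1477 and limma-voom 0, 0 and 1. With total counts in place of TMM factors 44.2% of 1110 changed genes were higher in NTCU, against 55.2% of 1232. The median log2 fold change over all genes tested was -0.13 in place of 0.02. The changes given here are relative to the TMM scaling.

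The 25-gene list of basal and squamous epithelium had 23 measured members, of which 14 rose, 9 did not pass and none fell (17 rose when adjusted over the list alone). Its median log2 fold change was 5.54, or 4.46 without NTCU replicate 1 (camera, adjusted p = 1.82e-10, or adjusted p = 0.512 with an estimated correlation). Krt5 (ENSMUSG00000061527; GRCm38 chromosome 15, 101707070 to 101712898, minus strand) rose by 10.60 ± 1.05 on the log2 scale (SE; edgeR, adjusted p = 0.00988). Krt14, also a keratin of basal cells, rose by 5.88 ± 0.88 (adjusted p = 0.0171). Trp63, the transcription factor that maintains basal cells (ENSMUSG00000022510; chromosome 16, 25683763 to 25892102, plus strand), rose by 5.54 ± 0.67 (adjusted p = 0.0136). Several genes of stratified epithelium had next to no counts in saline lungs. Krt17 had 1 count there, and its ratio of NTCU to saline was 1945 (95% counting interval 349 to 76850). For Krt6a, also with 1 count, the ratio was 1507 (270 to 59550), and for the desmosomal cadherin Dsg3 683 (122 to 27030). Pkp1, a plakophilin of desmosomes, had 0 counts in the saline libraries and was at least 279-fold higher in NTCU (3 counts over the group's libraries). Reads of keratins with near-identical paralogs, such as Krt6a, may be split between copies. In the list of squamous cornification, 7 of 15 measured members rose and none fell (8 adjusted over the list alone; median log2 fold change 2.08; camera, adjusted p = 9.10e-05, or adjusted p = 0.329 with an estimated correlation). Ly6d rose 11.4-fold, Tgm1, the transglutaminase that cross-links the cornified envelope, 6.41-fold and its substrate involucrin, Ivl, 4.22-fold (edgeR, adjusted p = 0.00973, 0.00984 and 0.0353). Without NTCU replicate 1, which had the highest value of each, the log2 fold changes were 9.51 for Krt5, 5.18 for Krt14 and 4.75 for Trp63, all still past the threshold. It was also highest in the genes with few saline counts, and without it the ratio was 916 (164 to 36243) for Krt6a and 131 (22.9 to 5252) for Dsg3, and Pkp1 was at least 83.1-fold higher. Without NTCU replicate 2 the ratio of Dsg3 was 1048. Without saline replicate 2 the ratios of Krt17, Krt6a and Dsg3 were 1283, 994 and 451, and Pkp1 was at least 184-fold higher. Without saline replicate 3, which held the 1 count of each, they were at least 413-fold, 320-fold and 145-fold higher, and Pkp1 at least 178-fold. Krt14 rose by 6.62 on the log2 scale without saline replicate 1. With NTCU replicate 3 left out 9 members of the first list and 3 of the second passed, and Krt14, Dsg3, Pkp1 and Ivl did not (adjusted p between 0.0543 and 0.117). Leaving out any 1 saline library left 0 members called by edgeR, 15 to 17 and 7 to 9 at an unadjusted p under 0.05, and 15 to 16 and 8 to 9 with DESeq2.

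**Figure D1:**
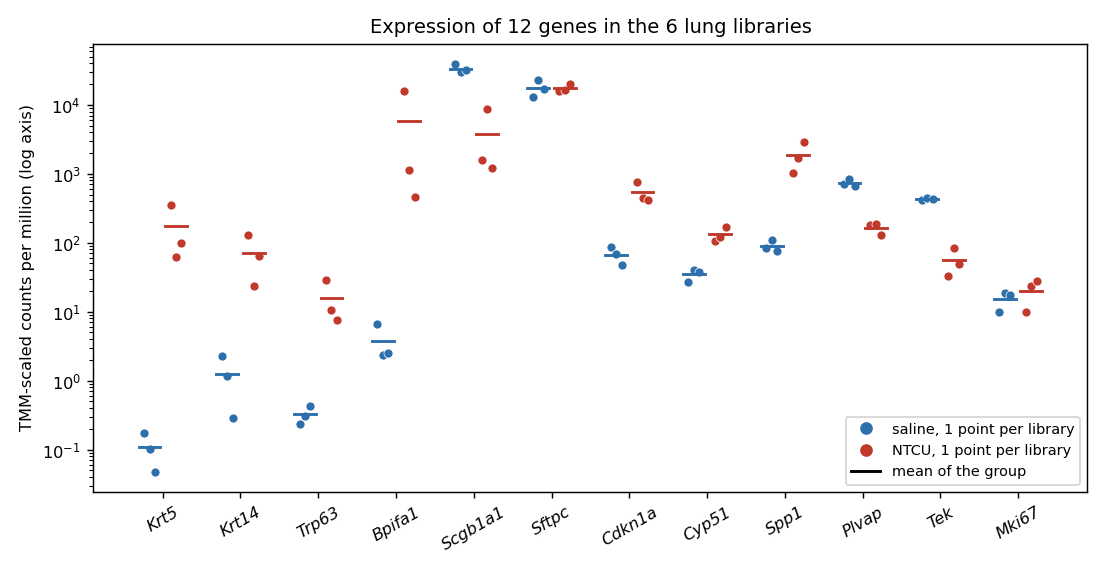
TMM-scaled CPM (log axis) of 12 genes in each library, saline in blue and NTCU in red, with a bar at the mean of each group of 3. Krt5 lies at 173 ± 161 CPM in NTCU and 0.108 ± 0.0636 in saline lungs, whereas Sftpc and Mki67 overlap between the groups.

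Among the other genes with the largest rises were Dmbt1, a scavenger glycoprotein of mucosal secretions, and Kng2, a kininogen. Both had 0 counts in the saline libraries and were at least 522-fold and at least 162-fold higher in NTCU, and 2210407C18Rik, also at 0 counts there, was at least 111-fold higher. Spink5, a serine protease inhibitor of stratified epithelium, had a ratio of 2469 (95% counting interval 443 to 97570), Clca3b of 1596 (286 to 63090) and Cyp4a12b, a cytochrome P450 with a near-identical neighbour, of 2668 (738 to 22040). The SD between NTCU lungs was as large as the mean or larger for some of these, as in Cyp4a12b (99.7 ± 162 CPM) and Spink5 (45.7 ± 66.5 CPM). The largest falls were those of Glp1r, the receptor of glucagon-like peptide 1, which fell 47.5-fold, Atp2b2, a calcium pump of the plasma membrane, which fell 29.7-fold, and Bex2, which fell 20.9-fold (edgeR, adjusted p = 0.0171, 0.0138 and 0.00988). Olfm2, Bcan, Iyd, the estrogen receptor Esr2, Nrgn and Grp, the gastrin-releasing peptide, fell as well, with log2 fold changes of -4.32, -3.84, -3.71, -3.59, -3.52 and -3.10. The adjusted p of Dmbt1, 0.0398, was 0.106 without NTCU replicate 1 and 0.0527 without NTCU replicate 2. With NTCU replicate 3 left out, Cyp4a12b, Glp1r, Bcan, Esr2, Nrgn and Grp did not pass (adjusted p between 0.0544 and 0.110), nor did 2210407C18Rik. Nrgn also missed without NTCU replicate 1 (0.0517), and no gene passed without any 1 saline library. The ratio was 175 (47.7 to 1451) for Cyp4a12b and 427 (76.0 to 16939) for Spink5 without NTCU replicate 1, and Dmbt1 was then at least 337-fold higher. Without NTCU replicate 2 that of Cyp4a12b was 4056. Without saline replicate 2 the ratios of Cyp4a12b, Spink5 and Clca3b were 1761, 1630 and 1053, and Dmbt1, Kng2 and 2210407C18Rik were at least 345-fold, 107-fold and 73.1-fold higher. Without saline replicate 3 those limits were 333, 103 and 70.5, Clca3b had a ratio of 1016 and Spink5 was at least 524-fold higher. Clca3b was at least 373-fold higher without saline replicate 1. Fitted log2 fold changes moved by over 1.5-fold in Bcan (-4.54 without NTCU replicate 1), Esr2 (-4.41 without NTCU replicate 2), Atp2b2 and Olfm2 (-5.75 and -4.95 without NTCU replicate 3) and Nrgn (-2.55 without saline replicate 1).

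Markers of club and secretory cells moved in both directions. Of 24 measured members 4 rose, 4 fell and 16 did not pass (7 and 7 adjusted over the list alone). The list did not pass as a whole (median log2 fold change 0.02; camera, adjusted p = 0.986). The median was below 0 under total-count scaling (-0.16), with the replicate block (-0.07) and without NTCU replicate 1 (-0.52) or saline replicate 2 (-0.07). The secreted airway proteins Bpifa1 and Reg3g rose by 10.59 and 8.85 on the log2 scale, and Agr2, a protein disulfide isomerase of mucous cells, by 6.58 (edgeR, adjusted p = 0.0220, 0.0218 and 0.0151). Bpifa1 was at 5840 ± 8753 CPM in NTCU lungs (SD, n = 3), with 15940, 1120 and 459 CPM in replicates 1, 2 and 3, and at 3.80 ± 2.35 CPM in saline lungs. Scgb3a1 rose too. Cckar, the cholecystokinin A receptor, fell 19.4-fold, and Cldn10, Chad and Aox3 also fell. Scgb1a1 (ENSMUSG00000024653; chromosome 19, 9083636 to 9087958, minus strand) was at 3795 ± 4137 CPM in NTCU and 33420 ± 4633 CPM in saline lungs. Its difference did not pass (log2 fold change -3.14 ± 0.78; adjusted p = 0.0567), but did without NTCU replicate 2 (adjusted p = 0.00629) and with DESeq2 (adjusted p = 3.88e-05). Scgb1a1 made up 0.139%, 0.868% and 0.117% of counts in NTCU replicates 1, 2 and 3. All 25 markers of ciliated cells had a log2 fold change below 0 (median -1.42, or -2.38 without NTCU replicate 2). Although none passed by itself, also when adjusted over the list alone, the list was lower (camera, adjusted p = 2.20e-07, or adjusted p = 0.564 with an estimated correlation). DESeq2 called 10 of them lower, and edgeR 2 without NTCU replicate 1 and 18 without NTCU replicate 2. Tppp3, a tubulin-binding protein, was at 193 ± 96.1 CPM in NTCU and 501 ± 40.0 CPM in saline lungs (adjusted p = 0.0851). Without NTCU replicate 1 the log2 fold changes of Bpifa1, Reg3g and Agr2 were 7.72, 6.83 and 5.67, and without NTCU replicate 2 those of Cckar, Scgb3a1 and Chad were -4.92, 2.86 and -3.36. With NTCU replicate 3 left out 3 club and secretory genes rose and 0 fell, and Cckar, Scgb3a1, Cldn10, Chad and Aox3 did not pass (adjusted p between 0.0655 and 0.112). Chad also missed without NTCU replicate 1 (0.0506) and Aox3 without NTCU replicate 2 (0.0686). Without any 1 saline library edgeR called 0 of them, against 5 to 7 higher and 6 to 7 lower at an unadjusted p under 0.05. DESeq2 called 5 to 7 and 5 to 6.

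Of 21 measured markers of alveolar type 2 cells 3 rose, none fell and 18 did not pass (4 rose and 1 fell adjusted over the list alone). The surfactant protein Sftpd rose 3.04-fold, the protease Ctsh 3.54-fold and the fatty acid binding protein Fabp5 4.53-fold (edgeR, adjusted p = 0.0138, 0.0162 and 0.0175). Sftpc, the surfactant protein made by these cells alone, was at 17670 ± 2352 CPM in NTCU and 17710 ± 5257 CPM in saline lungs (SD, n = 3; adjusted p = 0.995). The list had a median log2 fold change of 0.22 (camera, adjusted p = 0.0310, or adjusted p = 0.698 with an estimated correlation). Its call was lost without NTCU replicate 3 (adjusted p = 0.297) and without saline replicate 1 (adjusted p = 0.222). In the alveolar type 1 cell list 4 of 20 measured members rose, Col4a3, Col4a4, Pdpn and Spock2, and none fell (8 adjusted over the list alone; median log2 fold change 0.54; camera, adjusted p = 0.000493, or adjusted p = 0.564 with an estimated correlation). Podoplanin, Pdpn, rose 2.31-fold and the basement membrane collagen Col4a3 2.33-fold (edgeR, adjusted p = 0.0271 and 0.0222). Of 11 measured mesothelial markers Krt19 alone rose, 2.11-fold, a keratin that is also made by airway epithelium (3 adjusted over the list alone; camera, adjusted p = 0.00621, or adjusted p = 0.606 with an estimated correlation). The call of this list was lost without saline replicate 3 (adjusted p = 0.136). Without NTCU replicate 1, 6 alveolar type 2 and 2 mesothelial markers rose, without NTCU replicate 2, 6 alveolar type 1 and 3 mesothelial markers. With NTCU replicate 3 left out the counts were 1, 0 and 0, with Sftpd the only one of these genes to pass. For alveolar type 1 cells edgeR called 0 members without any 1 saline library, 8 at an unadjusted p under 0.05, and DESeq2 4 to 7.

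Genes of cholesterol biosynthesis rose together. Of 24 measured members 15 rose and 9 did not pass. All 24 had a log2 fold change above 0 (21 adjusted over the list alone; median change 2.29-fold; camera, adjusted p = 5.38e-12, or adjusted p = 0.389 with an estimated correlation). The lanosterol demethylase Cyp51 rose 3.79-fold, the sterol reductase Tm7sf2 3.58-fold and Hsd17b7 3.22-fold (edgeR, adjusted p = 0.0138, 0.0157 and 0.0139). Of 24 measured genes of cholesterol transport and efflux 6 rose and 1 fell (11 and 2 adjusted over the list alone; camera, adjusted p = 0.00406, or adjusted p = 0.377 with an estimated correlation). The scavenger receptor Msr1 rose 8.60-fold and the lipid carrier Apoe 2.48-fold, while the phospholipid transfer protein Pltp fell 2.20-fold (edgeR, adjusted p = 0.00988, 0.0220 and 0.0139). Abca1, the cholesterol exporter, was at 146 ± 54.5 CPM in NTCU and 72.9 ± 6.73 CPM in saline lungs. Its difference did not pass (log2 fold change 1.01 ± 0.26; adjusted p = 0.0649), but did without NTCU replicate 1 (0.0113), without NTCU replicate 2 (0.0391) and with DESeq2 (0.0101). In fatty acid and surfactant lipid synthesis 3 of 21 measured members rose, the desaturases Scd1 (8.61-fold) and Scd2 (2.66-fold) and the fatty acid synthase Fasn (2.82-fold), and none fell (6 adjusted over the list alone; camera, adjusted p = 0.000493, or adjusted p = 0.377 with an estimated correlation). None of 19 measured genes of fatty acid oxidation passed in edgeR, also when adjusted over the list alone, while DESeq2 called 3 lower, and edgeR 1 under total-count scaling and 1 without NTCU replicate 1 (median log2 fold change 0.08, below 0 under total-count scaling and in the direction of fry's test; camera, adjusted p = 0.911). Counts of genes that rose in the cholesterol biosynthesis, cholesterol transport and fatty acid synthesis lists were 20, 12 and 9 without NTCU replicate 1 and 4, 2 and 2 without NTCU replicate 3, where Scd2 did not pass (adjusted p = 0.0762). For cholesterol biosynthesis edgeR called 0 members without any 1 saline library, 19 to 21 at an unadjusted p under 0.05, and DESeq2 16 to 19.

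**Figure D2:**
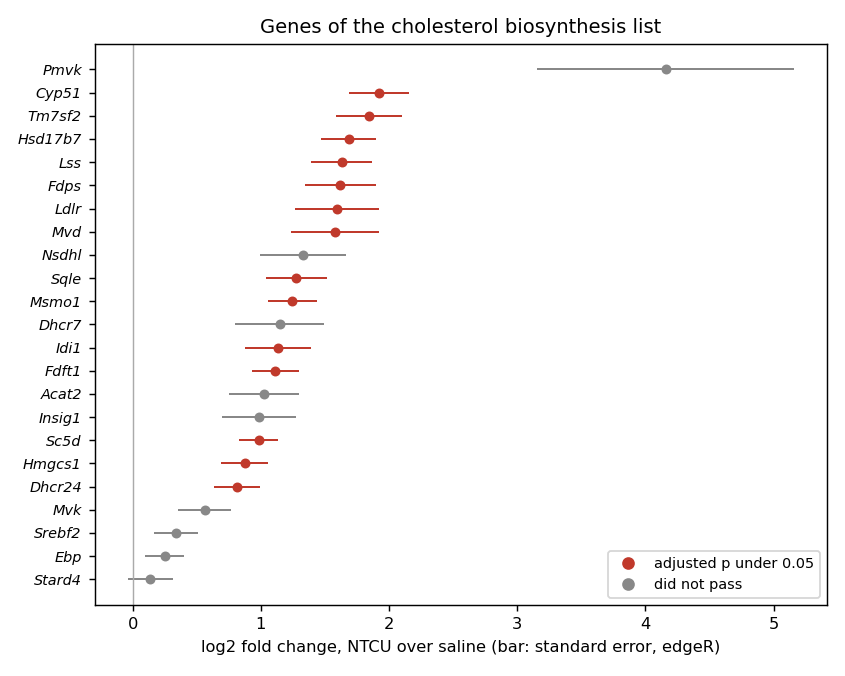
Log2 fold change of NTCU over saline for 23 genes of the cholesterol biosynthesis list, with bars of 1 standard error from edgeR, 14 genes past the threshold in red and 9 others in grey. All 23 points lie above 0, with Cyp51 at 1.92 and Tm7sf2 at 1.84.

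Targets of the tumour suppressor p53 rose. Of 23 measured members 11 rose, 12 did not pass and none fell (14 rose and 1 fell adjusted over the list alone; median log2 fold change 0.79; camera, adjusted p = 7.94e-08, or adjusted p = 0.329 with an estimated correlation). The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727, plus strand) was at 542 ± 189 CPM in NTCU and 67.3 ± 19.9 CPM in saline lungs (SD, n = 3). This was a rise of 3.01 ± 0.34 on the log2 scale (SE; edgeR, adjusted p = 0.0110). Eda2r rose 8.60-fold, Ccng1 3.90-fold and Zmat3 3.24-fold (adjusted p = 0.0124, 0.0109 and 0.0109). Among 25 measured targets of NRF2 and genes of glutathione metabolism 6 rose and none fell (11 and 1 adjusted over the list alone; camera, adjusted p = 0.000112, or adjusted p = 0.564 with an estimated correlation). Gclc, a subunit of the enzyme that limits glutathione synthesis, rose 3.67-fold and the cystine transporter Slc7a11 7.56-fold (edgeR, adjusted p = 0.0165 and 0.0279). The mean log2 CPM of this list was 6.73 in NTCU replicate 1 and 5.61 and 5.50 in NTCU replicates 2 and 3. In saline replicates 1, 2 and 3 it was 5.25, 5.16 and 5.08. The median log2 fold change of the list was 0.92, but 0.37 without NTCU replicate 1. Of 20 genes often altered in human lung squamous carcinoma 3 rose, Cdkn2a 16.9-fold, Myc 2.76-fold and Nfe2l2, which encodes NRF2, 1.58-fold (edgeR, adjusted p = 0.0151, 0.0398 and 0.0460; also 3 adjusted over the list alone). The list as a whole did not pass (median log2 fold change 0.15, below 0 under total-count scaling and without NTCU replicate 1; camera, adjusted p = 0.115), but did without NTCU replicate 3 (adjusted p = 0.0474). Sox2, a lineage factor of squamous carcinoma, did not pass (log2 fold change 0.04 ± 0.34; adjusted p = 0.949). None of 29 measured genes of cell cycle and proliferation passed, also when adjusted over the list alone, and DESeq2 called 0 of them (median log2 fold change 0.34; camera, adjusted p = 0.0604). This list was higher without NTCU replicate 1 (adjusted p = 0.000279, with 2 members called), without saline replicate 2 (0.00138) and under total-count scaling (0.0377). Of 16 measured genes of xenobiotic cytochrome P450 enzymes and their regulators only Ahr, a receptor that induces such enzymes, fell, 1.88-fold (1 rose and 5 fell adjusted over the list alone; camera, adjusted p = 0.0260, or adjusted p = 0.606 with an estimated correlation). The call of this list was lost without NTCU replicate 2 (0.0698) and replicate 3 (0.204), and with a filter of 1 CPM in 3 libraries (0.113). Counts of p53 targets, NRF2 targets and driver genes that rose were 13, 11 and 6 without NTCU replicate 1, where 2, 2 and 1 fell and 6 P450 genes were lower. The counts that rose were 5, 1 and 1 without NTCU replicate 3, with no P450 gene lower. In the absence of NTCU replicate 3 Gclc, Slc7a11, Myc, Nfe2l2 and Ahr did not pass (adjusted p between 0.0515 and 0.139), nor did Nfe2l2 and Ahr without NTCU replicate 2 (0.0686 and 0.0696). Nfe2l2 also missed under total-count scaling (0.121). Without NTCU replicate 1 the log2 fold changes of Cdkn2a and Slc7a11 were 3.30 and 2.17 in place of 4.08 and 2.92. For p53 targets edgeR called 0 members without any 1 saline library, 12 to 13 higher at an unadjusted p under 0.05, and DESeq2 10 to 11.

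Genes of macrophages rose. Of 23 measured members of the alveolar macrophage list 11 rose, 1 fell (Ear1) and 11 did not pass (16 and 2 adjusted over the list alone; median log2 fold change 1.32; camera, adjusted p = 1.65e-05, or adjusted p = 0.564 with an estimated correlation). The members did not move alike, as 17 had a log2 fold change above 0 and 6 below it. Besides Ear1 the latter were Fabp1 (-3.12), Siglecf (-0.79), Ear2 (-0.48), Krt79 (-0.46) and Car4 (-0.02), none of which passed. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 22.6-fold, osteopontin, Spp1 (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050, plus strand), by 4.39 on the log2 scale, the collagen-degrading protease Ctsk 11.9-fold and the lipid receptor Trem2 by 2.81 on the log2 scale (edgeR, adjusted p = 0.00984, 0.00988, 0.0109 and 0.00984). Spp1 was at 1880 ± 956 CPM in NTCU and 89.6 ± 16.7 CPM in saline lungs (SD, n = 3). In the list of monocytes and interstitial macrophages 9 of 21 measured members rose and none fell (10 and 1 adjusted over the list alone; camera, adjusted p = 0.000445, or adjusted p = 0.564 with an estimated correlation), with the lipopolysaccharide co-receptor Cd14 up 8.26-fold (edgeR, adjusted p = 0.00984). Of 20 measured complement genes C1qa, C1qb, C1qc and C3ar1 rose (10 adjusted over the list alone; camera, adjusted p = 0.000328, or adjusted p = 0.564 with an estimated correlation), with C1qb up 4.41-fold. Of 29 measured chemokines 8 rose and none fell (11 and 3 adjusted over the list alone; camera, adjusted p = 0.00422, or adjusted p = 0.621 with an estimated correlation). Cxcl17 rose 9.78-fold, the monocyte attractant Ccl2 8.83-fold and Ccl6 3.61-fold (edgeR, adjusted p = 0.0147, 0.0179 and 0.0189). Among 23 measured cytokines and inflammatory mediators the cytokines Il6 (14.0-fold) and Lif (3.33-fold) and the acute-phase proteins Saa3 (27.7-fold) and Lcn2 (13.9-fold) rose, and Nos2 fell (7 and 1 adjusted over the list alone; camera, adjusted p = 0.0167, or adjusted p = 0.632 with an estimated correlation). Of 19 measured neutrophil genes Lcn2, Clec4d and lactoferrin, Ltf, rose (5 adjusted over the list alone; camera, adjusted p = 0.0234, or adjusted p = 0.621 with an estimated correlation). Ltf and Lcn2 are also secreted by airway epithelium, and Ltf was at 5108 ± 6048 CPM in NTCU lungs. The calls of the chemokine, cytokine and neutrophil lists were lost without NTCU replicate 2 (adjusted p = 0.0676 for each), and that of the neutrophil list also without NTCU replicate 1 (0.130) and saline replicate 2 (0.730). Counts of members that rose in the alveolar macrophage, complement, chemokine and cytokine lists were 15, 10, 18 and 10 without NTCU replicate 1. In the absence of NTCU replicate 3 those in the alveolar macrophage, chemokine, cytokine and neutrophil lists were 8, 3, 2 and 1, and C3ar1, Ccl2, Il6, Lif, Ltf, Clec4d, Ear1 and Nos2 did not pass (adjusted p between 0.0537 and 0.130). The log2 fold change of Ltf, which rose 128-fold, was 5.36 without NTCU replicate 1 and 8.15 without saline replicate 3, and that of Il6, 3.81, was 4.72 without saline replicate 2. In the alveolar macrophage list edgeR called 0 members without any 1 saline library, 14 to 16 higher at an unadjusted p under 0.05, and DESeq2 12 to 16. Total-count scaling left 5 chemokines higher and 1 lower.

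Lists of lymphocytes were lower at camera's preset correlation, with fewer single genes past the threshold. All 15 measured genes of natural killer and cytotoxic cells had a log2 fold change below 0 (median -1.81). Of these Prf1, the pore-forming perforin, fell 7.45-fold and the receptor Klrd1 4.05-fold (edgeR, adjusted p = 0.0341 and 0.0284; 9 adjusted over the list alone; camera, adjusted p = 6.42e-06, or adjusted p = 0.564 with an estimated correlation). Of 23 measured T cell genes only Tcf7, a transcription factor of naive T cells, fell, 2.19-fold (3 adjusted over the list alone; camera, adjusted p = 0.00351, or adjusted p = 0.621 with an estimated correlation). None of 20 measured B cell genes passed in edgeR, also when adjusted over the list alone, whereas DESeq2 called 4 lower (median log2 fold change -1.19; camera, adjusted p = 0.000620, or adjusted p = 0.621 with an estimated correlation). Pax5, the B lineage factor, had a log2 fold change of -2.09 ± 0.53 (adjusted p = 0.0600). Mean log2 CPM of these lists was lowest in NTCU replicate 1, at -1.41 against 0.94 and 0.41 in NTCU replicates 2 and 3 for natural killer cells and at 1.03 against 2.51 and 2.08 for T cells. Of 17 measured genes of plasma cells and immunoglobulins the heavy chain Ighg1 rose 12.5-fold and Sdc1, also made by epithelium, 1.87-fold, and the plasma cell regulator Prdm1 fell 1.96-fold (8 and 1 adjusted over the list alone; camera, adjusted p = 0.00756, or adjusted p = 0.621 with an estimated correlation). The list of type I and II interferon response was lower (median log2 fold change -0.67; camera, adjusted p = 0.000664, or adjusted p = 0.606 with an estimated correlation). In it Ido1 and Gbp3 fell and Ifit3 rose, of 28 measured members (also 2 and 1 adjusted over the list alone), and Ifit3 missed under total-count scaling (0.0710). The list of dendritic cells did not pass (camera, adjusted p = 0.0853), but did without NTCU replicate 2 (0.0197) and replicate 3 (0.0341), with 3 of its 17 measured members lower, Clec9a, Ccr7 2.34-fold and Zbtb46 2.49-fold (also 3 adjusted over the list alone). None of 19 measured genes of MHC class I antigen presentation passed in edgeR (camera, adjusted p = 0.347). DESeq2 called 1 higher and 1 lower, as did edgeR without NTCU replicate 1. In MHC class II antigen presentation 1 of 14, the protease Ctss, rose (2 adjusted over the list alone), and the camera test pointed up while the median was -0.18 (adjusted p = 0.986), or 0.25 and 0.01 without NTCU replicate 1 and saline replicate 3. In the list of mast cells, eosinophils and basophils 1 of 14, the receptor Kit, fell (1 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.130). The T cell list lost its call without NTCU replicate 1 (0.133) and the plasma cell list without NTCU replicate 2 (0.101) and with mitochondrial, hemoglobin and immunoglobulin genes removed (0.209). Without NTCU replicate 1, 6 natural killer, 3 T cell and 6 B cell genes fell and 10 plasma cell and immunoglobulin genes rose. With NTCU replicate 3 left out Prf1, Klrd1, Tcf7, Ighg1, Sdc1, Prdm1, Ido1, Gbp3, Ifit3, Clec9a, Ccr7, Zbtb46 and Ctss did not pass (adjusted p between 0.0543 and 0.129). For natural killer cells edgeR called 0 members without any 1 saline library, 7 to 10 at an unadjusted p under 0.05, and DESeq2 3 to 8.

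Endothelial genes fell. All 24 measured members had a log2 fold change below 0 (median -1.43). In edgeR 17 fell and 7 did not pass (20 adjusted over the list alone; camera, adjusted p = 2.06e-12, or adjusted p = 0.329 with an estimated correlation). Plvap, a component of endothelial diaphragms (ENSMUSG00000034845; chromosome 8, 71497765 to 71511752, minus strand), was at 166 ± 30.9 CPM in NTCU and 738 ± 90.1 CPM in saline lungs (SD, n = 3). This was a change of -2.15 ± 0.20 on the log2 scale (SE; edgeR, adjusted p = 0.00984). Tek fell 7.82-fold, its homologue Tie1 4.43-fold and the guidance receptor Robo4 3.35-fold (adjusted p = 0.0118, 0.0109 and 0.0139). The apelin receptor Aplnr fell, with a log2 fold change of -3.70, and Esm1, a proteoglycan of endothelial tip cells that is not in the list, fell 19.3-fold (adjusted p = 0.0167 and 0.00984). All 19 measured genes of smooth muscle and pericytes had a log2 fold change below 0 (median -0.66). Smtn, Higd1b and Cox4i2 fell, by 1.79-fold, 2.16-fold and 2.43-fold (edgeR, adjusted p = 0.0336, 0.0379 and 0.0408; 5 adjusted over the list alone; camera, adjusted p = 0.000214, or adjusted p = 0.564 with an estimated correlation). None of 20 measured fibroblast genes passed in edgeR, also when adjusted over the list alone, and DESeq2 called 4 lower. The fibroblast list was lower (median log2 fold change -0.42; camera, adjusted p = 0.0260, or adjusted p = 0.606 with an estimated correlation), but not without NTCU replicate 1 (0.0711), NTCU replicate 3 (0.0861) or saline replicate 1 (0.0522), nor under total-count scaling. Of 9 measured erythroid genes 5 fell (also 5 adjusted over the list alone; median log2 fold change -1.48; camera, adjusted p = 0.000445, or adjusted p = 0.564 with an estimated correlation). Among them were the globins Hba-a1 (3.49-fold), Hba-a2, Hbb-bs and Hbb-bt, whose near-identical copies may share reads. The call of the erythroid list was lost with mitochondrial, hemoglobin and immunoglobulin genes removed (0.0971). The endothelial list fell in the same lungs in which the share of hemoglobin transcripts was lower, 0.0834% against 0.288%. Without NTCU replicate 1 and replicate 3, 22 and 6 endothelial genes fell. Without NTCU replicate 2, 6 genes of smooth muscle and pericytes fell, and without NTCU replicate 3 none of these, nor any erythroid gene. Aplnr and the named muscle, pericyte and erythroid genes did not pass without NTCU replicate 3 (adjusted p between 0.0623 and 0.120), nor did Hbb-bs without NTCU replicate 2 (0.0523). For the endothelial list edgeR called 0 members without any 1 saline library, 19 to 20 at an unadjusted p under 0.05, and DESeq2 18.

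Genes of the extracellular matrix rose in part. Of 27 measured genes of fibrillar collagen and interstitial matrix Thbs1, Fn1, Col5a2, Tnc and Vcan rose and none fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.0303, or adjusted p = 0.377 with an estimated correlation). Thrombospondin 1, Thbs1, rose 5.70-fold, fibronectin, Fn1, 3.52-fold and tenascin C, Tnc, 4.04-fold (edgeR, adjusted p = 0.00973, 0.0179 and 0.0310). Col1a1, the main collagen of fibrous tissue, was at 135 ± 55.6 CPM in NTCU and 124 ± 16.3 CPM in saline lungs (SD, n = 3; adjusted p = 0.836). Of 22 measured basement membrane genes 8 rose and none fell (11 and 1 adjusted over the list alone; camera, adjusted p = 9.10e-05, or adjusted p = 0.473 with an estimated correlation). The heparan sulfate proteoglycan Hspg2 rose 2.19-fold (edgeR, adjusted p = 0.0267). Of 29 measured matrix remodelling enzymes and inhibitors 7 rose and none fell (11 adjusted over the list alone; camera, adjusted p = 0.000112, or adjusted p = 0.329 with an estimated correlation). The metalloproteinase Mmp19 rose 11.6-fold and the inhibitor Timp1 by 3.09 on the log2 scale (edgeR, adjusted p = 0.0110 and 0.0143). Of 30 measured genes of cell junctions 6 rose and Cdh5 and Cldn10 fell (9 and 5 adjusted over the list alone; camera, adjusted p = 0.0217, or adjusted p = 0.564 with an estimated correlation). The desmosomal cadherin Dsc2 rose 16.3-fold and the tight junction protein Cldn2 15.0-fold, and Cdh5, the cadherin of endothelium, fell 2.73-fold (edgeR, adjusted p = 0.0171, 0.0309 and 0.0311). Of 24 measured integrins Itga7, Itgav, Itga3 and Itgb2 rose and Itga1 fell (7 and 3 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.164). Calls were lost for the fibrillar collagen list without NTCU replicate 2 (0.0601) and for the junction list without NTCU replicate 1 (0.0692). Counts of members that rose in the matrix remodelling and integrin lists were 12 and 8 without NTCU replicate 1. Without NTCU replicate 3 they were 2 for fibrillar collagen, 0 for basement membrane, 2 for matrix remodelling, 1 for junctions and 0 for integrins. Under total-count scaling they were 3, 5, 4, 5 and 2 in the same order, and Col1a1 turned to -0.01. Among the genes named, Col5a2, Tnc, Vcan, Hspg2, Cldn2, Cdh5, Cldn10 and the integrins did not pass without NTCU replicate 3 (adjusted p between 0.0559 and 0.111). The log2 fold change of Dsc2 was 3.32 in place of 4.03 without NTCU replicate 1 and that of Cldn2 3.07 in place of 3.91 without NTCU replicate 2. For matrix remodelling edgeR called 0 members without any 1 saline library, 10 to 12 at an unadjusted p under 0.05, and DESeq2 8.

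**Figure D3:**
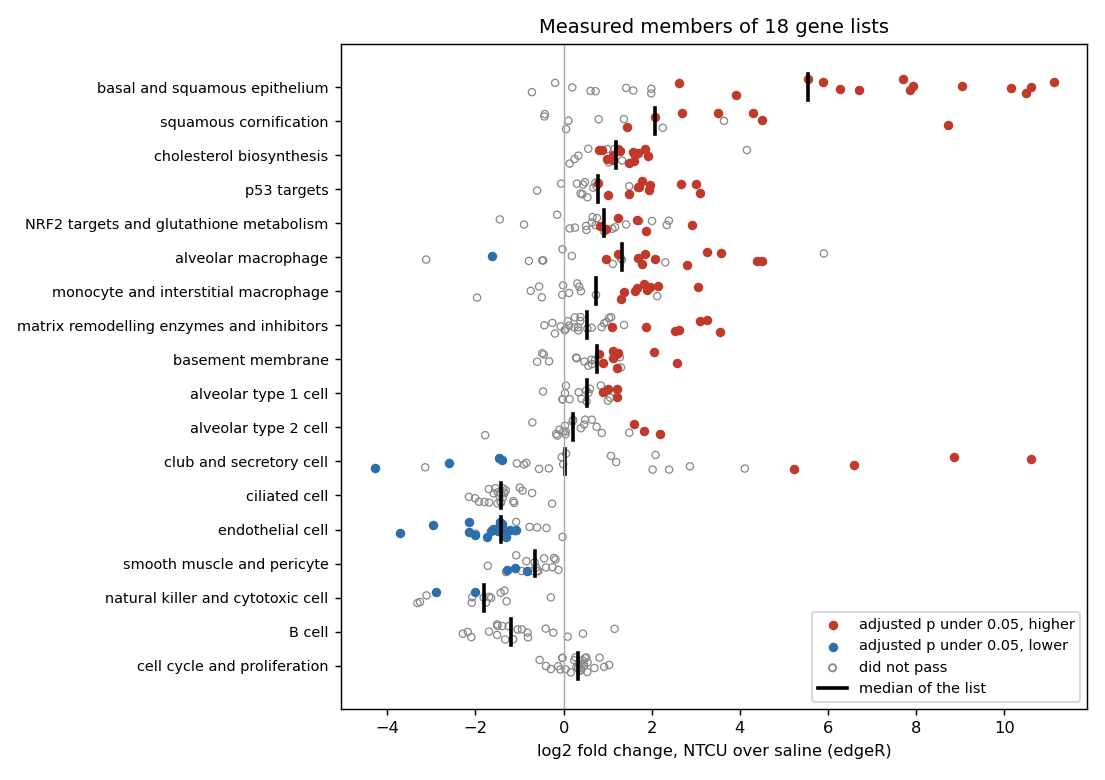
Log2 fold change of NTCU over saline for each measured member of 18 gene lists, filled red (higher) or blue (lower) where the adjusted p from edgeR was under 0.05 and open otherwise, with a black bar at the median of each list. The median was 5.54 for basal and squamous epithelium (4.46 without NTCU replicate 1), 0.79 for p53 targets and -1.43 for endothelial cells, and that of club and secretory cells, 0.02, fell below 0 under total-count scaling and without NTCU replicate 1 (-0.52).

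Genes of stress and glycolysis rose, and the remaining lists did not pass. Of 20 measured immediate early and heat shock genes, a group that also responds to tissue handling, Atf3, Socs3, Dnajb1, Hspa1b and Junb rose and none fell (9 and 2 adjusted over the list alone; camera, adjusted p = 0.000664, or adjusted p = 0.329 with an estimated correlation). Atf3 rose 3.57-fold and Hspa1b, which has a near-identical copy, 9.97-fold. Of 20 measured genes of hypoxia and glycolysis Ldha, Pgam1, Gapdh, Hk2 and Eno1 rose and none fell (8 and 1 adjusted over the list alone; camera, adjusted p = 0.00373, or adjusted p = 0.389 with an estimated correlation). Hexokinase 2, Hk2, rose 4.57-fold. Of 7 measured thymocyte genes Satb1, a chromatin organiser, fell (2 adjusted over the list alone; camera, adjusted p = 0.259). No member passed in edgeR in the lists of cardiac muscle (13 measured; adjusted p = 0.854), skeletal muscle (6; 0.724), adipocytes (11; 0.583), the circadian clock (17; 0.103), replication-dependent histones (8; 0.806) and mitochondrially encoded genes (12; 0.986). DESeq2 called 1 adipocyte gene higher and 2 lower, 1 clock gene higher and 2 histone genes higher. In edgeR 1 skeletal muscle gene and 1 histone gene were higher and 2 adipocyte genes lower without NTCU replicate 1, and 1 histone gene was higher and 1 adipocyte gene lower without NTCU replicate 2. With RLE factors 1 adipocyte gene was lower. The adipocyte median was 0.48 with the camera test pointing down, and it was -0.86 without NTCU replicate 2 and -0.73 with the replicate block. The clock list passed under total-count scaling (0.0311) and without NTCU replicate 2 (0.0409), NTCU replicate 3 (0.0284) or saline replicate 3 (0.00919). Its mean log2 CPM was 6.26 in NTCU replicate 1 and 4.65 and 4.57 in NTCU replicates 2 and 3. Cardiac muscle passed as lower without NTCU replicate 2 (0.0476) and as higher without NTCU replicate 3 (0.0341), and mitochondrially encoded genes as lower without saline replicate 3 (0.0423). Counts of genes that rose in the immediate early and glycolysis lists were 9 and 8 without NTCU replicate 1 and 2 and 0 without NTCU replicate 3, where Dnajb1, Hspa1b, Junb, Satb1 and the glycolysis genes named did not pass (adjusted p between 0.0543 and 0.143). The same held for Satb1 without NTCU replicate 2 (0.0547). Junb and Eno1 also missed under total-count scaling (0.0769 each), and the log2 fold change of Hk2, 2.19, was 1.56 without NTCU replicate 1. In both lists edgeR called 0 members without any 1 saline library, 9 to 10 and 6 to 8 at an unadjusted p under 0.05, and DESeq2 6 to 7 and 4 to 5. In all, 33 of 49 lists tested passed with camera's preset correlation, 23 higher and 10 lower. With an estimated correlation 0 passed, although 5 had an unadjusted p under 0.05. With fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, 15 passed.

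**Figure D4:**
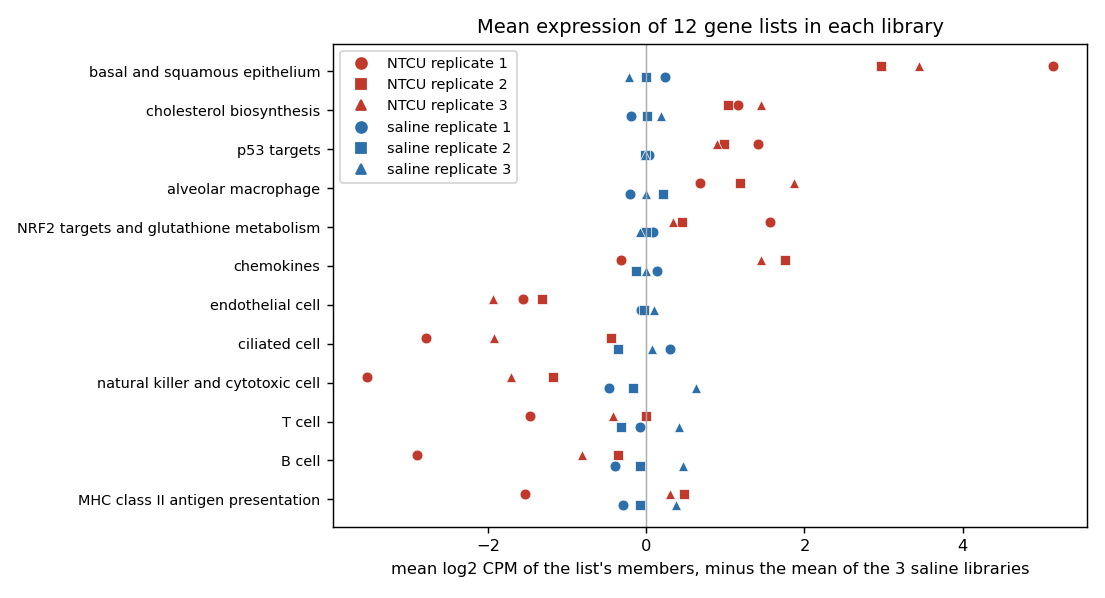
Mean log2 CPM of the members of 12 gene lists in each library, minus the mean of the 3 saline libraries, with NTCU in red, saline in blue and the replicate given by the shape. NTCU replicate 1 lies apart from the other NTCU libraries in several lists, as in NRF2 targets (mean log2 CPM 6.73 against 5.61 and 5.50) and ciliated cells (1.72 against 4.06 and 2.58).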

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

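The loess correction on GC content and length and the counts of list members without single libraries are tests chosen only after the result was seen. Against 1232 changed genes (680 higher, 552 lower), DESeq2 called 2802 (1557, 1245), limma-voom with quality weights 4010 (2102, 1908) and an adjusted p under 0.01 left 33 (22, 11). Leaving out 1 library gave 0 to 3233 (higher 0 to 1756, lower 0 to 1477). Of 33 lists, 0 passed with an estimated correlation, 15 with fry and 0 with fry and a replicate block. At its preset correlation camera called 35 lists with that block, all 33 among them. With 1 library left out it called 30 to 34, among them 27 to 32 of the 33. The labels do not say whether replicate numbers mark anything shared. Same-numbered libraries correlated in their deviations from the group means at 0.0453, -0.196 and 0.00242, and not every library correlated best with its own number. Deviations from a group mean cancel out within the group, so these correlations cannot exclude a day or batch shared by equal numbers. With the replicate block 264 genes were called (166, 98), and 263 with RLE factors (166, 97). No changed gene reversed in any setting. Genes that had not passed changed sign near 0. Col1a1 was at -0.00550 with total counts and between -0.14 and 0.42 with 1 library left out. Sftpc was at 0.00480 with RLE factors, 0.00826 with DESeq2, 0.0320 with limma-voom, 0.0325 with the block, 0.0846 after the loess correction and between -0.19 and 0.24 with 1 library left out. Sox2 was at -0.12 with total counts, -0.0619 with limma-voom, -0.0580 with the block and between -0.18 and 0.36 with 1 library left out. The cause was not tested.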

Other observations

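All tests here were chosen only after the result was seen, except the GC content and length test and the test of the second glucocorticoid set, both for NTCU replicate 1, which were written down before they were run.

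Further lists were drawn up after the values had been seen, some of them with genes already reported, so no test of a list is given for them. Of 17 measured acute-phase proteins 11 rose, among them Orm1 (log2 fold change 8.12), Saa3 (4.79), Lcn2 (3.80) and Lbp (1.93). Of 6 measured ligands of the EGF receptor, which drive growth of squamous epithelium, Ereg (6.57), Areg (3.60) and Hbegf (1.71) rose. Of 13 measured cathepsins 8 rose, such as Ctsd (2.18) and Ctsb (1.63), and 5 of 20 measured subunits of the vacuolar proton pump, such as Atp6v0c (1.13), rose as well. The alveolar macrophage list, which shares members with both, rose too (median 1.32), as did that of monocytes and interstitial macrophages (0.73), with an adjusted p of 0.564 for each at an estimated correlation. Of 17 measured genes of the Notch pathway 6 fell, among them the endothelial ligand Dll4 (-2.86), Nrarp (-1.99) and Notch4 (-1.98), while the endothelial list fell with a median of -1.43 (adjusted p = 0.329 with an estimated correlation). In the cholesterol biosynthesis list Pmvk had the largest log2 fold change, 4.16 (adjusted p = 0.0523), of which 2.15 remained without NTCU replicate 1, where it was at 1046 CPM against 87.6 and 120 in NTCU replicates 2 and 3. Leaving out any 1 saline library left no changed gene in edgeR, these included.

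NTCU replicate 1 stood apart from the other NTCU libraries. Its depth, 17.87 M reads, lay within the range of the others, and the SD over genes of its difference from them was 1.92 times that between NTCU replicates 2 and 3 after correction for GC content and length, so neither explains it. The ciliated list was lower in it, 1.72 against 4.06 and 2.58, but the club and secretory list was highest in it, 6.92 against 6.77 and 5.24, so a larger piece of conducting airway remains open. All 15 genes of a first set of glucocorticoid-induced genes were higher in it than in the other 5 libraries, the observation that prompted a test on a second set of 15 genes. There the median difference from NTCU replicates 2 and 3 was 0.74, above the 95th percentile of 10000 matched sets (0.37) but below the value of 1 fixed beforehand, so a glucocorticoid response remains open.

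Endothelial genes fell while alveolar type 1 genes did not (adjusted p = 0.329 and 0.564 with an estimated correlation). The median of the alveolar type 1 list was 0.54, which argues against dilution of all alveolar cells alike, and the endothelial median was -1.40 after correction for GC content and length. Of the 24 members, 5 lay further than 3 standard errors from the median of the list. That only meets the bound of 5, which was set after the values had been seen, so whether all members fell alike remains open. Neither outcome could tell fewer cells from altered expression. Some members are also genes of other cells, such as Car4 (-0.02), which is in the alveolar macrophage list too.

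Cholesterol biosynthesis genes rose, with a median of 1.22 after correction for GC content and length (adjusted p = 0.389 for the uncorrected list with an estimated correlation). The alveolar type 2 list, whose cells make surfactant lipid, had a median of 0.22, which argues against a larger share of these cells as the source. The alveolar macrophage list rose by a similar amount, with a median of 1.32 (adjusted p = 0.564 with an estimated correlation), so a larger share of macrophages remains open. Of its 23 measured members 6 had a log2 fold change below 0.

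Of the 10 ways to split the libraries into 3 and 3, only 1, the real one, gave as many changed genes (1232, against 0 in the highest other), and only 1 as many changed lists (33, against 32). With 10 splits no share under 0.05 is possible. The splits that mix the groups gave between 15 and 32 lists, so camera at its preset correlation called many lists in every split. Such splits are not balanced, so part of the group difference may remain in them.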
